A study of Rattus norvegicus with 8 samples.

How the data were processed

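Liver RNA of 8 male F344/N rats was measured on NimbleGen 1-colour (Cy3) expression arrays, with 4 rats that received thioacetamide for 28 days and 4 untreated controls kept on basal diet and tap water. Thioacetamide is a liver toxicant that needs bioactivation by liver enzymes. The dose is not given in the sources used here. The labels give gavage as the route for both groups, and their protocol says that controls received no treatment. Per the labels, each group held 4 animals, so the p-values measure the spread between animals.

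The deposited values are gene-level log2 expression values, 1 per probe set and array. Per the submitters' processing notes they were made with RMA, a method that corrects background, normalizes between arrays and summarises the probes of a probe set. Its version and settings, the scanner, the slide layout and the annotation build are not given in the sources used here. The files held 26208 probe sets per array, of which 19600 were summarised from 3 probes, 6592 from 2 and 16 from 1, and 1 random control set of 37 probes, which was left out. The deposited log2 values of the series table and of the sample files were identical (largest difference 0). In the array of control replicate 4, 11 probe sets had no value. These values were tested as deposited. The design written before the data were examined assumed raw probe intensities with background correction, quantile normalization and median polish. Those steps were not repeated, since the deposited values had already been through RMA and raw intensities were not used here.

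Probe sets were named through the gene identifiers in the files and a RefSeq table of the GRCr8 assembly: 20543 matched by gene identifier, 31 by accession, and 5634 kept the symbol of the files. No coordinates are given because the build of the array is not named. The probe sets stood for 24137 genes, 1855 of them with several probe sets. For gene-level statements the probe set with the highest mean over all 8 arrays was used.

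Thioacetamide was compared with control on the log2 scale with limma 3.58.1 (lmFit and eBayes, no intensity trend, not robust) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all 26208 probe sets and a threshold of 0.05. Differences are thioacetamide minus control, and errors on them are standard errors of the fit unless SD is written. Standard errors of list medians are taken over the genes of the list. No block was used. The 4 headline numbers were the probe sets changed, higher, lower, and changed at least 2-fold (a log2 difference of at least 1). Before the data were examined, 34 gene lists with 656 entries were fixed, of which 646 were matched. Each was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 34 lists. Camera with an estimated correlation and fry were run beside it. Counts of list members use the adjustment over all probe sets, and counts adjusted over the list alone are given where stated. Some lists share genes, for example 10 of the 28 phase I metabolism genes and 9 of the 13 periportal hepatocyte genes stand in another list. Both the log2 difference and the list tests were tested on simulated data. Of 100 probe sets given a 2-fold change, 19% were recovered, and of 100 given a 4-fold change, 77% were recovered, in a simulation of 26197 probe sets for this comparison, with 6 false among 102 calls. A raised list was recovered, and 1 of 100 random lists reached an unadjusted p under 0.05. The simulated noise was drawn independently for each probe set, so false list calls from correlated genes could not show. Far fewer probe sets were changed there than passed in the real comparison, so the recovered shares may differ from those in the real data.

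Named genes followed a rule fixed before the data were examined: the 12 largest rises and the 12 largest falls among changed probe sets with non-overlapping groups, for each list the 3 changed members with the largest difference and the largest one of the opposite direction (or the 2 largest where none changed), and a fixed set of genes chosen for their known part in thioacetamide toxicity or liver damage. The rule gave 127 genes, and the text names most of them. A few of these genes are not reported here.

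Array files give no depth, and the number of arrays limits the precision. The signal over background stands in for it. A level per array was taken as the 95th percentile of its 1226 olfactory receptor probe sets, which a liver is not expected to express; this definition was chosen after seeing the data. Where a group lay at or under this level on every array, only a bound on the fold is given. The bound sets the bright group's mean against the dim group's mean of the higher of the level and the measured value.

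Alternatives tried were median centring, cyclic loess, a filter on dim probe sets, an intensity trend with robust estimation, array weights, the replicate number as a block, leaving out each array, fry, and the mean over the probe sets of a gene. After seeing the data, quantile normalization of the deposited values, a filter on the olfactory receptor level and a fit without 3 arrays were added. Background correction, probe summary, and slide or scan batches could not be varied from the values used here.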

Results

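Genome-wide liver expression was measured in 8 male F344/N rats, 4 untreated and 4 given thioacetamide for 28 days, to find how the toxicant changed the liver transcriptome. The arrays gave values for 26208 probe sets (26197 in control replicate 4), with a median log2 level between 7.27 and 7.40. The level of the olfactory receptor probe sets, taken as background, ranged from 6.95 to 7.94 in controls and from 6.54 to 6.95 in treated rats, and 43.1% to 54.3% of probe sets lay above it in controls against 55.2% to 61.0% in treated rats. The first principal component held 51.7% of the variance and separated the groups, while the second, with 19.8%, separated control replicates 2 and 3 and thioacetamide replicate 4 from the others of their group. Control replicate 3 correlated least with its group (mean r across probe sets 0.9346, against 0.9545 to 0.9592 for the other controls; probe sets are not independent replicates).

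**Figure D1:**
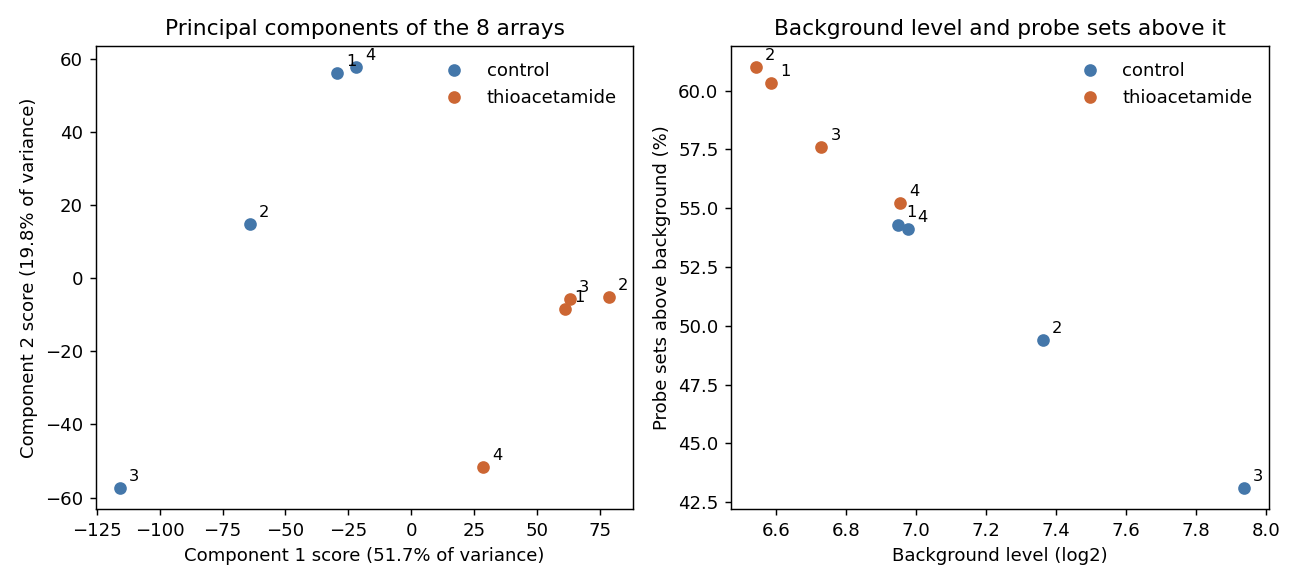
Left, scores of the 8 arrays on the first and second principal component of all probe sets; right, the background level (95th percentile of the olfactory receptor probe sets, log2) against the percentage of probe sets above it. Points are arrays, numbered by replicate; control replicate 3 has the highest background level (7.94) and the lowest percentage (43.1%).

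Thioacetamide changed the expression of a large part of the liver transcriptome. The largest rises included genes of drug transport, glutathione and acyl-CoA metabolism, and the largest falls included male-typical and hepatocyte-specific enzymes. Of 26208 probe sets, 3827 changed, with 2480 higher and 1347 lower, and 2663 of them changed at least 2-fold (1722 higher, 941 lower). At an unadjusted p under 0.05 there were 7739. Over all 26208 probe sets, 5634 had groups that did not overlap, where chance gives 2.86%. Per gene, 3597 of 24137 changed. The counts depended on single treated arrays: 2166 probe sets changed without thioacetamide replicate 2 (1447 higher, 719 lower) and 2466 without replicate 1 (1638 higher, 828 lower). The balance of directions depended on scaling, since cyclic loess gave 1998 higher and 1736 lower (53.5% higher, against 64.8%). Without control replicates 2 and 3 and thioacetamide replicate 4, an alternative added after seeing the data, 4139 changed, with 2282 higher and 1857 lower.

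Among the largest rises, Abcb1b, a multidrug efflux pump, was at least 78.4-fold higher, with controls at or under background on all arrays (measured means 6.74 ± 0.39 and 13.60 ± 0.14, SD, n = 4 each, adjusted p = 2.2e-07). Acot1, a cytosolic acyl-CoA thioesterase, was at least 35.9-fold higher (adjusted p = 2.18e-07), Ddr1, a collagen receptor, at least 15.9-fold (adjusted p = 1.65e-06) and Soat1, which esterifies cholesterol, at least 15.4-fold (adjusted p = 1.68e-05). Gpx2, a glutathione peroxidase, rose 47.3-fold (log2 difference 5.56 ± 0.31), with 1 of 4 control arrays above background. Akr1b8, an aldo-keto reductase, rose 37.4-fold (5.23 ± 0.36), and Gstm3 (described in the files as transferase M4) and Gsta3, glutathione transferases, rose 34.5-fold and 31.8-fold. Nefm, a neurofilament gene, rose 33.5-fold (5.07 ± 0.44). A further pair, LOC687842 (at least 22.0-fold higher) and Cyp2c55 (29.5-fold), are both described in the files as similar to one cytochrome P450, and a second probe set of Cyp2c55 gave 0.15 ± 0.25 (adjusted p = 0.736), so signal shared between related genes cannot be separated. Of the control arrays, 3 of 4 were above background for Gstm3, Gsta3 and Cyp2c55 and 2 of 4 for Nefm. LOC682044, a hypothetical protein in the files, was at least 23.8-fold higher.

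The largest measured falls were Stac3 (190-fold, log2 difference -7.57 ± 0.22, adjusted p = 1.55e-07), Inmt (at least 84.8-fold, with treated rats at or under background), Dhrs7l1 (142-fold) and Aox3, an aldehyde oxidase (126-fold, -6.98 ± 0.30). Hsd3b5, a male-typical steroid dehydrogenase, fell 53.1-fold (-5.73 ± 0.29) and Nox4, an NADPH oxidase, was at least 27.9-fold lower. LOC688253, similar to a urinary protein, fell 45.2-fold, Mup4l3, an alpha-2u globulin, fell 22.5-fold, and Sez6 fell 24.5-fold. Cyp2c11 fell 37.8-fold, Cyp3a9 (described in the files as a different family 3 member) 29.9-fold and Oat, ornithine aminotransferase, 28.7-fold. Of the treated arrays, 2 of 4 were above background for Stac3, 3 of 4 for Dhrs7l1 and 1 of 4 for Aox3, so the size and order of these folds rest partly on values under background. All the rises and falls named here kept the threshold in each of the 8 fits with 1 array left out.

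**Figure D2:**
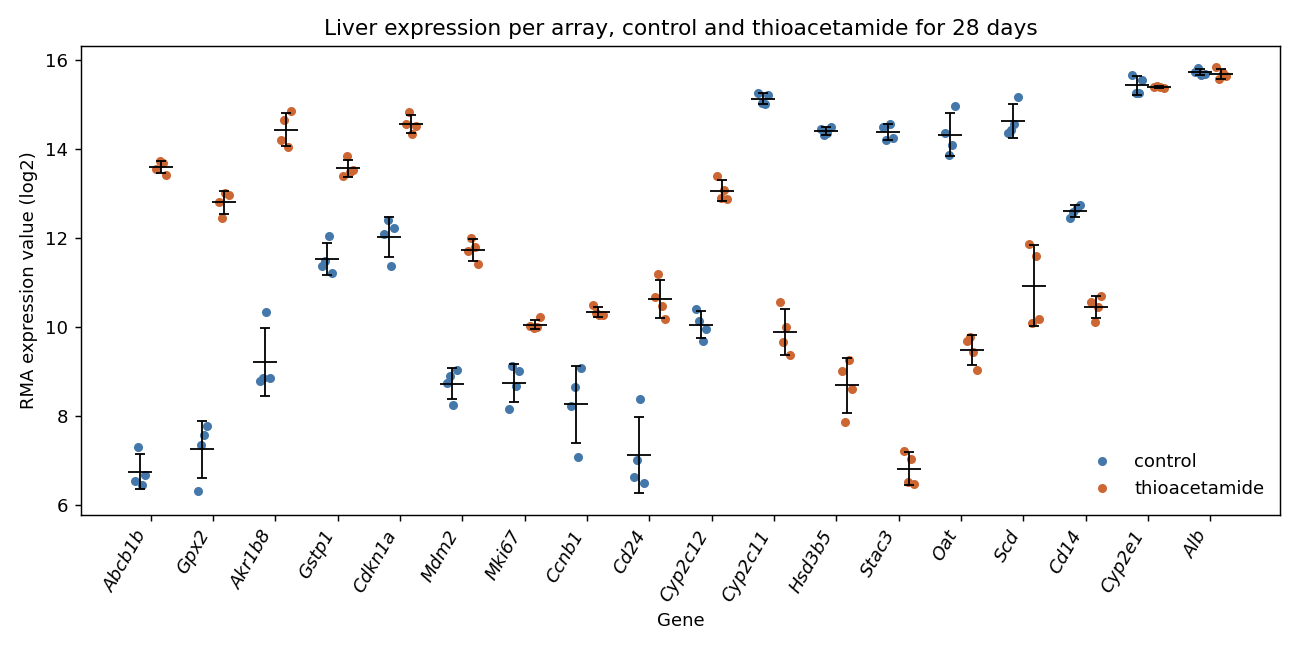
RMA expression values (log2) of 18 genes named in the text in each of the 4 control (blue) and 4 thioacetamide (orange) arrays; points are arrays, bars the mean and SD. Abcb1b and Stac3 lie at opposite ends in the 2 groups, and Alb and Cyp2e1 lie near the highest values of the arrays (15.89 to 15.98), where differences can be compressed.

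Most genes of the Nrf2 and glutathione response rose. Of 24 measured members, 15 rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 difference of 1.5 (camera adjusted p = 1.55e-10, adjusted p = 0.0608 with an estimated correlation). Abcc3, a bile acid and conjugate exporter, rose 19.7-fold (4.30 ± 0.24), with 2 of 4 control arrays above background. Gsta2 was the member that fell (-1.27 ± 0.21). In the list of preneoplastic and fetal liver genes, 7 of 15 rose and 0 fell (8 and 0 at an unadjusted p under 0.05 in limma, and 8 and 0 adjusted over the list alone), with a median of 1.14 (camera adjusted p = 1.44e-07, adjusted p = 0.205 with an estimated correlation). Gstp1, the placental glutathione transferase used as a marker of altered foci in rat liver, rose 4.10-fold (2.04 ± 0.23, adjusted p = 0.000386), and Akr7a3, an aflatoxin aldehyde reductase, rose 12.7-fold. Gstp1, Akr7a3 and Gpx2 are the 3 members that also stand in the Nrf2 and glutathione list, so the rises of these lists are partly the same genes. Afp, alpha-fetoprotein, differed by 0.83 ± 0.41 (adjusted p = 0.206), which did not pass.

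Cell cycle genes were higher in treated livers, together with targets of p53. Of 28 genes of G2/M and mitosis, 20 rose and 0 fell (24 and 1 at an unadjusted p under 0.05 in limma; 24 and 1 adjusted over the list alone), with a median of 1.27 (camera adjusted p = 3.04e-12, adjusted p = 0.116 with an estimated correlation). Ccnb1, cyclin B1, rose by 2.08 ± 0.37 (4.23-fold), Aurkb by 2.06 ± 0.35 and Cdk1 by 1.43 ± 0.22, and Mki67, the gene of the Ki-67 antigen, rose 2.50-fold (1.32 ± 0.24, adjusted p = 0.00488). Racgap1 was at least 1.32-fold higher. Top2a rose by 1.21 ± 0.28 (adjusted p = 0.0175), and lost the threshold under cyclic loess (0.95, adjusted p = 0.0527), with the replicate block (1.21, adjusted p = 0.0787), without thioacetamide replicate 1 (1.08, adjusted p = 0.0598) and without replicate 3 (1.19, adjusted p = 0.0505). Of 22 genes of G1/S and DNA replication, 10 rose and 0 fell (17 and 0 at an unadjusted p under 0.05, and 17 and 0 adjusted over the list alone), with a median of 1.11 (camera adjusted p = 7.56e-09, adjusted p = 0.116 with an estimated correlation), and 5 passed without thioacetamide replicate 1 and 5 without replicate 2. Tyms, thymidylate synthase, rose 5.65-fold (2.50 ± 0.19). Of these 50 genes, 21 were above background on all arrays, and in controls 3 of 4 arrays were for Ccnb1 and Aurkb and 1 of 4 for Cdk1. Of 15 p53 targets, 11 rose and 0 fell (12 and 0 at an unadjusted p under 0.05, and 12 and 0 adjusted over the list alone), with a median of 2.20 (camera adjusted p = 9.11e-11). This list alone kept its call with an estimated correlation (adjusted p = 0.0338). Fas, a death receptor, rose 8.97-fold (3.17 ± 0.39, with 3 of 4 control arrays above background), Mdm2, which targets p53 for degradation, 8.05-fold (3.01 ± 0.23), Ccng1 6.24-fold and Cdkn1a, an inhibitor of cyclin-dependent kinases, 5.85-fold (2.55 ± 0.25).

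**Figure D3:**
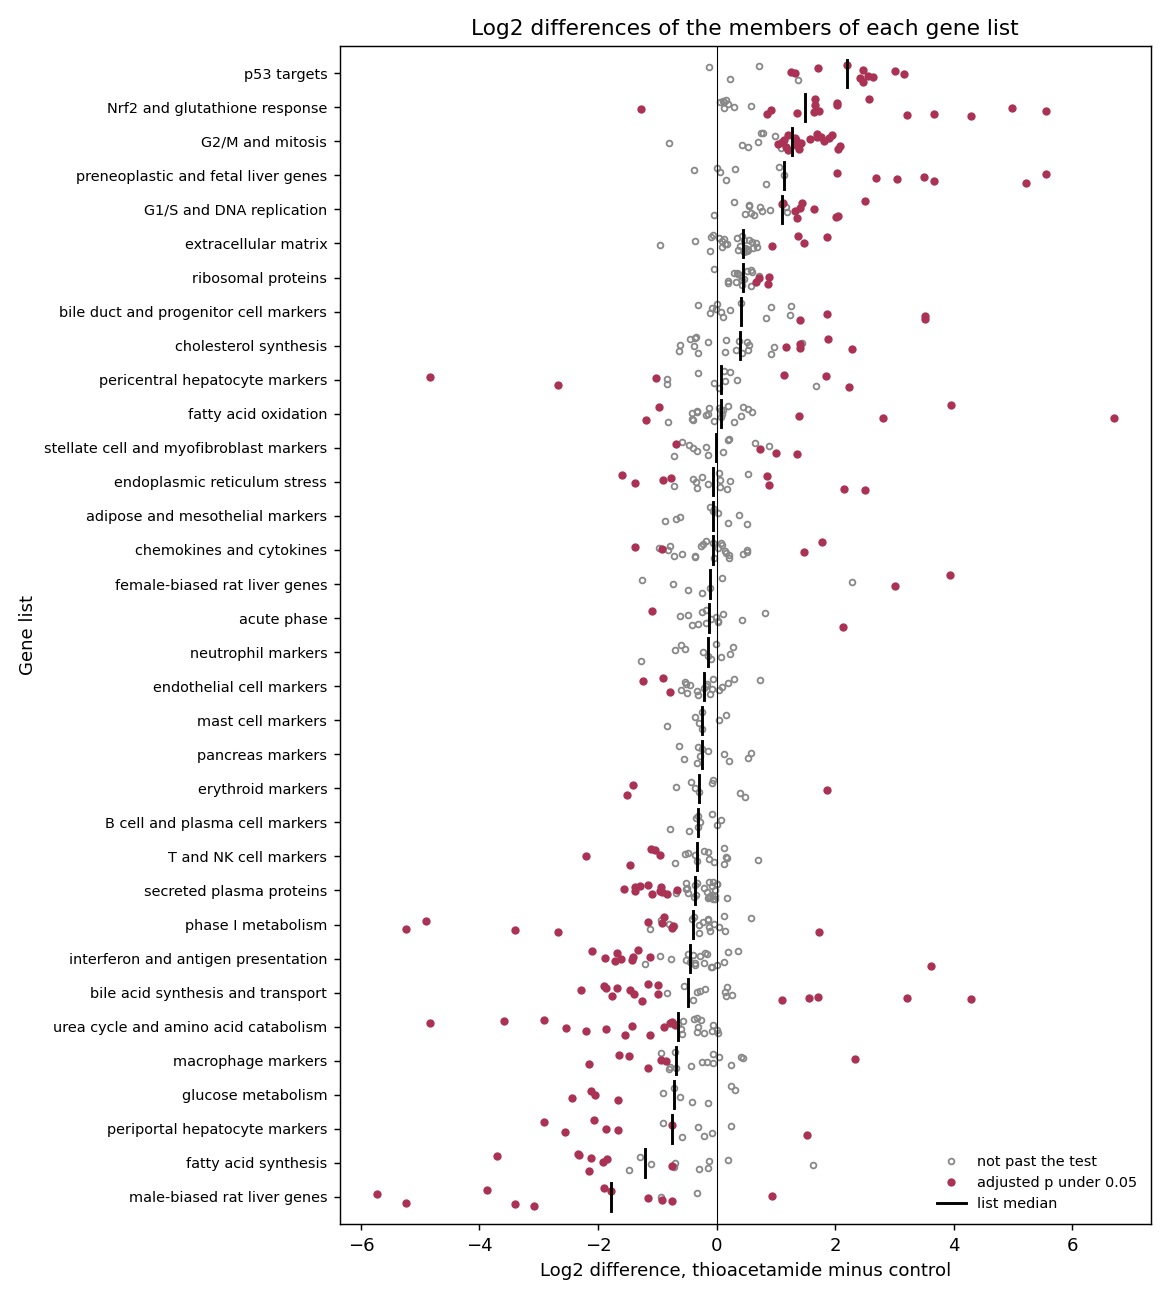
Log2 difference (thioacetamide minus control) of every measured member of the 34 gene lists, with members past the adjusted p filled and the others open; the black line is the list median. The p53 list has the highest median (2.20) and the male-biased list the lowest (-1.78).

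Sex-dependent liver genes changed in both directions. Of 13 male-biased rat liver genes, 10 fell and 1 rose, with a median of -1.78 (camera adjusted p = 2.39e-09, adjusted p = 0.105 with an estimated correlation; 11 and 1 adjusted over the list alone). Cyp2c11 and Hsd3b5 led the list, and Obp3 fell 14.7-fold (-3.87 ± 0.36). Dhrs7 rose by 0.93 ± 0.18, whereas Dhrs7l1, whose probe set the files describe as a member 7 dehydrogenase, was among the largest falls. Of 9 female-biased genes, Sult2a2, a sulfotransferase, rose by 3.94 ± 0.39 (1 of 4 control arrays above background) and Cyp2c12 by 3.01 ± 0.22 (8.05-fold), and a second probe set of Sult2a2 gave 0.51 ± 0.52 (adjusted p = 0.556). The median of that list was -0.11 and its mean 0.72, with opposite signs, and the list test did not pass (camera adjusted p = 0.545). Adjusted over the list alone, 2 rose and 2 fell.

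A part of the listed enzymes of drug and amino acid metabolism was lower. In phase I metabolism 9 of 28 genes fell and 1 rose (median -0.40, camera adjusted p = 9.67e-06, adjusted p = 0.277 with an estimated correlation), and 5 fell without control replicate 2, 5 without control replicate 4 and 5 without thioacetamide replicate 1. The rise was Cyp1a1 (at least 2.02-fold higher, adjusted p = 0.0252), and it lost the threshold without control replicates 1 and 4 (adjusted p = 0.0587 and 0.0511) and without thioacetamide replicates 1, 2 and 3 (adjusted p = 0.0765, 0.0779 and 0.0634). Cyp2a2 fell 10.5-fold. Of the enzymes that bioactivate thioacetamide, Cyp2e1 differed by -0.03 ± 0.18 (adjusted p = 0.922; positive, 0.05, under cyclic loess, and near the highest values of the arrays, where a difference can be hidden) and Fmo1 by 0.58 ± 0.24 (adjusted p = 0.128). In urea cycle and amino acid catabolism 13 of 27 fell and 0 rose (16 and 0 at an unadjusted p under 0.05), with a median of -0.65 (camera adjusted p = 7.75e-10, adjusted p = 0.238 with an estimated correlation), and Prodh, proline dehydrogenase, fell 12-fold. Of 13 periportal genes 6 fell and 1, Cdh1 (1.53 ± 0.27), rose (median -0.75, camera adjusted p = 0.000472, adjusted p = 0.277 with an estimated correlation), with Sds, serine dehydratase, 7.50-fold lower. Of 16 pericentral genes 3 rose and 3 fell, with Aldh1a1 at 2.23 ± 0.34 and Cyp1a2 at -2.68 ± 0.22. The median (0.08) and the mean (-0.17) differed in sign, the median was -0.01 under cyclic loess, and the list test did not pass (camera adjusted p = 0.649). With fry the pericentral list passed as lower (adjusted p = 0.0399). Adjusted over the list alone, the phase I, amino acid, periportal and pericentral lists had 13, 16, 8 and 5 falls and 1, 0, 1 and 4 rises.

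Lipid, bile acid and glucose genes also changed. In fatty acid synthesis 8 of 18 fell and 0 rose (12 and 0 at an unadjusted p under 0.05), with a median of -1.20 (camera adjusted p = 3.68e-06, adjusted p = 0.327 with an estimated correlation). Scd, stearoyl-CoA desaturase, fell 13-fold (-3.70 ± 0.42). In glucose metabolism 4 of 11 fell and 0 rose (8 and 0 at an unadjusted p under 0.05, median -0.71, camera adjusted p = 0.000522, adjusted p = 0.277 with an estimated correlation), and Pklr, liver pyruvate kinase, fell 4.34-fold. Of 26 genes of bile acid synthesis and transport 11 fell and 5 rose (median -0.48, camera adjusted p = 0.0153, adjusted p = 0.572 with an estimated correlation). That list lost its call without control replicate 4 (median -0.51, adjusted p = 0.0593) and without thioacetamide replicate 4 (median -0.39, adjusted p = 0.0676), and 3 members rose without thioacetamide replicate 1. The exporters Abcc3 and Abcc4 (9.24-fold, 3 of 4 control arrays above background) rose, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.14 ± 0.45 (adjusted p = 0.869). In cholesterol synthesis 5 of 24 rose and 0 fell (8 and 0 at an unadjusted p under 0.05, median 0.40), among them Sqle, squalene epoxidase, 3.68-fold (1.88 ± 0.30), but the list call (camera adjusted p = 0.0489, adjusted p = 0.735 with an estimated correlation) was lost in 5 of the 8 fits with an array left out (without control replicates 1, 2 and 3 and thioacetamide replicates 1 and 3, medians 0.41, 0.36, 0.36, 0.40 and 0.19, adjusted p = 0.0913, 0.129, 0.137, 0.0661 and 0.46), and 3 of its members rose without any one of control replicates 1 and 2 and thioacetamide replicates 1 and 3. Of 27 genes of fatty acid oxidation 4 rose and 2 fell, and the list test did not pass (camera adjusted p = 0.545). Vnn1 rose by 3.96 ± 0.56 in that list (3 of 4 control arrays above background), and its falls numbered 0 without control replicate 4, thioacetamide replicate 2 or thioacetamide replicate 4, and 1 without control replicate 1, 2 or 3 or thioacetamide replicate 1. Adjusted over the list alone, fatty acid synthesis, glucose, bile acid, cholesterol and fatty acid oxidation genes gave 11, 6, 12, 0 and 3 falls and 0, 0, 5, 6 and 4 rises.

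Markers of other cell types did not move alike. Of 17 bile duct and progenitor markers 4 rose and 0 fell (8 and 0 at an unadjusted p under 0.05, median 0.42, camera adjusted p = 0.00242, adjusted p = 0.343 with an estimated correlation). Under the olfactory receptor filter this list lost its call (adjusted p = 0.0559), with a median of 0.67 over the members left. Cldn7 rose 11.5-fold, Cd24 11.4-fold (2 and 1 of 4 control arrays above background) and Epcam 3.64-fold, whereas Krt19, a bile duct keratin, differed by 0.08 ± 0.53 (adjusted p = 0.937; -0.16 under cyclic loess). Of 30 extracellular matrix genes 4 rose and 0 fell (10 and 0 at an unadjusted p under 0.05, median 0.45, camera adjusted p = 0.00355, adjusted p = 0.415 with an estimated correlation), with 2 rising without control replicate 2 and 2 without thioacetamide replicate 2, and its call was lost under the olfactory receptor filter (adjusted p = 0.0661, median 0.47 over the members left). Thbs1, thrombospondin 1, rose by 1.86 ± 0.31 (2 of 4 control arrays above background), while Col1a1 differed by 0.51 ± 0.38 (adjusted p = 0.412) and Tgfb1 by 0.05 ± 0.24 (adjusted p = 0.920, negative under median centring and cyclic loess). Of 16 stellate cell and myofibroblast markers 3 rose and 1 fell, with median and mean of opposite sign (-0.02 and 0.10, the median positive under cyclic loess and quantile normalization) and no call (camera adjusted p = 0.649). Cygb rose by 1.35 ± 0.21 (1 of 4 control arrays above background) and Acta2, smooth muscle actin, differed by -0.71 ± 0.43 (adjusted p = 0.309). Of the stellate markers 1 rose without control replicate 1 or thioacetamide replicate 1, 2 or 3, and 0 fell without control replicate 1 or 2 or any one thioacetamide replicate. Of 21 macrophage markers 6 fell and 1 rose (median -0.68, camera adjusted p = 0.00399, adjusted p = 0.482 with an estimated correlation): Cd14 fell 4.46-fold and Gpnmb rose 5.06-fold. Without thioacetamide replicate 2 it was 2 that fell and without replicate 3 it was 3. Without control replicate 3, 2 rose and the list call was lost (median -0.515, adjusted p = 0.0514). Of 19 T and NK cell markers 5 fell and 0 rose (5 and 1 at an unadjusted p under 0.05, median -0.33, camera adjusted p = 0.0153, adjusted p = 0.277 with an estimated correlation), with Gzma, granzyme A, 4.62-fold lower. It was 3 without control replicate 1, 3 without thioacetamide replicate 2 and 3 without replicate 3, and the list call was lost without replicate 4 (median -0.31, adjusted p = 0.0676). Of 21 endothelial markers 3 fell and 0 rose (6 and 0 at an unadjusted p under 0.05, median -0.20, camera adjusted p = 0.0272, adjusted p = 0.415 with an estimated correlation). Of these, 1 fell without any one of thioacetamide replicates 1, 2 and 3, and the list call was lost without control replicate 4 (median -0.14, adjusted p = 0.143) and without thioacetamide replicate 4 (median -0.20, adjusted p = 0.168). The endothelial median lay near that of the olfactory receptor probe sets (-0.217), which the liver is not expected to express. However, 15 of the 21 endothelial markers were above background on all control arrays. No B cell, neutrophil, mast cell, pancreas, or adipose and mesothelial marker changed in the main limma fit (0 of 9, 11, 7, 11 and 10; at an unadjusted p under 0.05, 1, 3, 0, 1 and 3), and their list tests did not pass (camera adjusted p = 0.241, 0.323, 0.456, 0.649 and 0.649). Above background on all control arrays were 2 of 9 B cell, 0 of 11 neutrophil and 0 of 7 mast cell markers. For pancreas it was 0 of 11 and for adipose and mesothelial markers 2 of 10. Most of these markers were thus too dim for the lack of calls to show that the cell types did not change. Other fits gave calls in the neutrophil and pancreas lists. Ltf, a neutrophil marker, passed without thioacetamide replicate 4 (-0.99, adjusted p = 0.0188) and without control replicates 2 and 3 and thioacetamide replicate 4, the 3 arrays in doubt (-0.93, adjusted p = 0.0357). Camp, another, passed with array weights (adjusted p = 0.0467) and without the arrays in doubt (adjusted p = 0.0137). Camp was at or under background on all treated arrays, so only a bound is given (at least 1.63-fold lower with all arrays). Without control replicate 4, 1 neutrophil marker was lower. Of the pancreas markers 1 was lower without control replicate 3 and without the arrays in doubt, and 1 was higher under cyclic loess and quantile normalization. Erythroid markers gave 1 rise and 2 falls among 11 (camera adjusted p = 0.545), and the falls numbered 0 without thioacetamide replicate 1 and 0 without replicate 2, and 1 without any one of control replicates 2, 3 and 4 and thioacetamide replicates 3 and 4. Adjusted over the list alone, bile duct, matrix, stellate, macrophage, T and NK cell, endothelial and erythroid markers gave 7, 4, 4, 1, 0, 0 and 1 rises and 0, 0, 1, 10, 5, 2 and 2 falls, and the lists with no change gave 0.

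Immune and stress genes showed mixed directions. Of 29 interferon and antigen presentation genes 9 fell and 1 rose (median -0.45, camera adjusted p = 0.000412, adjusted p = 0.277 with an estimated correlation). Ubd, a ubiquitin-like modifier, fell 4.27-fold (-2.10 ± 0.37) and Cxcl10, a chemokine, rose 12.3-fold (3.62 ± 0.36). Of 26 chemokines and cytokines 2 rose, Tnfaip3 (1.78 ± 0.20) and Cxcl1 (1.48 ± 0.34), each with 1 of 4 control arrays above background, and 2 fell, including Il1rn (-1.38 ± 0.28), and the list test did not pass (camera adjusted p = 0.588). The falls numbered 4 without control replicate 4 and 1 without any one of control replicates 2 and 3 and thioacetamide replicates 1, 2 and 3. Of 16 acute phase genes A2m, alpha-2-macroglobulin, rose 4.37-fold (2 of 4 control arrays above background) and 1 fell, a call lost without control replicates 1 and 2 and thioacetamide replicates 1 and 2 (0 fell), with 2 rising without thioacetamide replicate 4, and the list test did not pass (camera adjusted p = 0.540). Of 36 secreted plasma proteins 11 fell and 0 rose (13 and 0 at an unadjusted p under 0.05, median -0.36, camera adjusted p = 7.38e-06, adjusted p = 0.277 with an estimated correlation), with F7, coagulation factor VII, 2.94-fold lower and Alb, albumin, at -0.03 ± 0.17 (adjusted p = 0.926; positive under cyclic loess and quantile normalization, and near the highest values of the arrays, where a difference can be hidden). Of 20 endoplasmic reticulum stress genes 4 rose, including Asns (2.51 ± 0.31, 2 of 4 control arrays above background) and Atf3 (at least 2.58-fold higher), and 4 fell, including Sdf2l1 (-1.59 ± 0.23). In this list 2 rose without thioacetamide replicate 1, and 2 fell without thioacetamide replicate 1, 2 or 3. Its median (-0.05) and mean (0.04) differed in sign, and the test did not pass (camera adjusted p = 0.649). Of 20 ribosomal protein genes 4 rose and 0 fell (11 and 0 at an unadjusted p under 0.05, median 0.44, camera adjusted p = 6.49e-05, adjusted p = 0.277 with an estimated correlation), led by Rplp0 (0.89 ± 0.18) and Rpl19 (0.87 ± 0.17), with 2 rising without any one of control replicates 1 and 2 and thioacetamide replicates 1 to 4. Adjusted over the list alone, interferon, chemokine, acute phase, plasma protein, stress and ribosomal genes gave 11, 2, 1, 12, 5 and 0 falls and 1, 2, 1, 0, 4 and 7 rises.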

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

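Of the tests of explanations here, those on plasma proteins, the female-biased list, a rise of all other cell types alike, and non-parenchymal cells behind the cell cycle genes were chosen after the results were seen. For the male-biased genes the rise of all other types alike was judged by 3 rules in turn: the macrophage median alone (-0.684, standard error 0.203) argued against it, the same median in 3 fits (-0.36, standard error 0.211, in the weakest) left it open, and the gap between medians, as used for control replicate 3, was over 2 standard errors. Since the rules were changed after their results were seen, the question is left open. That gap is between the 2 extremes of 4 lists, with no correction for their choice. Standard errors of medians in this section are taken over the genes of a list. Such genes are not independent replicates, so these errors can be too small. The others and the splits of the arrays were fixed before their results. The value of 1 array lay far from the other 3 of its group in 12 of 322 groups tested. Chance would flag about 1 in 20 independent groups, or 16.1 of these. Many of the genes were chosen by their change between groups, and genes and lists share the same arrays. Whether the number is in excess can thus not be judged. Of the 12, 6 were in control replicate 3.

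In control replicate 3, Akr1b8 was at 10.34 (the other controls 8.79 to 8.86), Cyp2c55 at 7.39 (8.86 to 9.08), Uroc1 at 12.40 (13.11 to 13.24), Tgfb1 at 11.15 (10.18 to 10.30), Afp at 10.10 (10.94 to 11.11) and the mean of the periportal list at 13.48 (13.92 to 14.01). Control replicate 4 had Lox at 6.99, Tnfaip3 at 6.52 and the mean of the Nrf2 and glutathione list at 11.31. Thioacetamide replicate 3 had Sqle at 12.45 and Hmgcs1 at 14.67, and thioacetamide replicate 4 had the mean of the neutrophil list at 6.70.

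The array of control replicate 3 stood apart, with the lowest correlation with its group. Noise among transcripts that liver should not hold was tested by the spread of olfactory receptor differences between controls: the smallest SD of a pair with this array was 0.759 and the largest without it 0.722, a ratio of 1.05, which leaves noise open. A gain of other cell types was tested by marker medians of this array minus the other controls, which were -0.0684 (standard error 0.226) for stellate markers, 0.728 (0.217) for bile duct markers, 0.628 (0.111) for macrophage and 0.181 (0.164) for endothelial markers. The bile duct and stellate medians differed by 0.796 (standard error 0.313), so these lists did not move alike in this array. With 1 array and errors taken over genes, the gap cannot decide whether a lower hepatocyte share raised all other types alike. A gain of bile duct cells or macrophages may contribute and stays open, and the design gives no biological group to test.

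Male-biased genes were lower in treated livers. Noise of control replicate 3 is argued against, since 8 of the 10 lower members passed without it. Loss of hepatocytes stays open: all 36 plasma protein genes had a median of -0.356, against a male-biased median of -1.78, but most of them had a control level of 14 or more, where differences can be compressed, and the 9 with a control level under 14, a limit set after seeing the data, had a median of -0.944 (standard error 0.135). A lower hepatocyte share that raised all other cell types alike stays open. The highest and lowest of 4 marker medians, bile duct and macrophage, differed by 1.1 (standard error 0.35) with all arrays, 1.11 (0.366) without control replicate 3 and 0.864 (0.384) without the 3 arrays in doubt. This gap takes the extremes, under a rule set after earlier ones, with errors over genes, so it cannot decide. A change in bile duct cells or macrophages themselves stays open too. A shift towards the female pattern, a biological explanation through the treatment, cannot be told apart from other causes: the female-biased median was -0.111 (standard error 0.619), with members going both ways.

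Cell cycle genes were higher in treated livers (median 1.18 over 50 genes). Noise of control replicate 3 and of dim probe sets is argued against, since the median was 1.24 (standard error 0.132) over the 21 members above background on all arrays without that array. More cells of a non-parenchymal type stay open: the highest median among 7 marker lists was 0.417, for bile duct markers, and a small dividing share can stay hidden below markers with a high baseline. Division of hepatocytes or of another cell type after the treatment was not tested here.

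The counts were also set against all 35 splits of the 8 arrays into 4 and 4. In limma, only 1 split, the real one, gave as many changed probe sets (3827, against 0 in the highest other split), probe sets higher (2480, against 0), probe sets lower (1347, against 0) or probe sets changed at least 2-fold (2663, against 0). A share of 1 in 35 is the smallest that these splits can give, so they cannot exclude chance by themselves. The 4 counts come from the same fit and are not separate tests. At an unadjusted p under 0.05 the real split gave 7739 and the highest other split 4223. The other splits mix treated and control arrays, which raises the spread within their groups.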

How the results depend on the processing

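Alternatives chosen after seeing the data were quantile normalization of the deposited values, the filter on the olfactory receptor level and the fit without 3 arrays. Planned but not run were other background corrections and a mean over probes, since raw intensities were not used here, and a block for slide or scan, since none was given in the sources used here. The authors' deposited values are the main ones. The planned percentile of random control probes could not be had from 1 summarised set, so its fallback, above the bottom 25% of probe sets in at least 4 arrays, was run.

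Leaving out 1 array, the probe sets changed ranged from 2166 to 3924, those higher from 1447 to 2436, those lower from 719 to 1488 and those changed at least 2-fold from 1865 to 3129. The first 3 counts fell by more than 1.5 times without thioacetamide replicate 1 or 2, and the cause was not tested. With the replicate block, 2163 changed, 1475 higher and 688 lower, and 1994 at least 2-fold, and the cause was not tested. The sources used here do not say that the replicate numbers pair animals. Correlations of same-numbered deviations from the group means were 0.246, -0.0983, -0.126 and -0.431, and no control correlated best with its own number. These deviations include those of the 3 arrays in doubt, so they give no sign of a pairing but cannot exclude one. Under the other settings the counts of changed probe sets ranged from 3637 (median centring) to 4988 (array weights). No scaling moved the median of all probe sets by over 0.1.

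Of 678 comparisons of a list with its main result 630 stayed on the same side of the threshold, lists without a call included, 47 lost a call and 1 gained one, and no call turned direction. The estimated correlation alone ended 20 of the 21 list calls. Cholesterol synthesis accounted for 12 of the 27 other losses and endothelial markers for 5. Without the 3 arrays in doubt, the macrophage, T and NK cell, endothelial and cholesterol lists lost their call (medians -0.36, -0.205, -0.268 and 0.358, adjusted p = 0.184, 0.13, 0.0916 and 0.206). Under the olfactory receptor filter the bile duct, extracellular matrix and cholesterol lists lost theirs (medians 0.667, 0.466 and 0.404, adjusted p = 0.0559, 0.0661 and 0.366), and with fry the macrophage, endothelial, bile acid and cholesterol lists did (adjusted p = 0.0864, 0.0712, 0.106 and 0.278). The 1 gained call was that of the pericentral list, lower with fry (adjusted p = 0.0399). Of 2148 comparisons of named genes 2040 stayed on the same side of the threshold, uncalled genes included, 102 lost a call and 6 gained one. Of the 108 named genes called, 91 passed in all 8 fits with an array left out, and 14 lost the threshold with the replicate block. Signal over background limits the 7579 probe sets above it on no array, of which 50 changed, and 2 lists, mast cell and pancreas, had no member left under the olfactory receptor filter.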

Other observations

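The families below were defined after seeing the data, by the letters that symbols share, with at least 10 genes each. Of 244 families tested with camera, 40 passed at an adjusted p under 0.05, and with an estimated correlation none did (lowest adjusted p = 0.476). Of 10 Utp genes, which act in the processing of ribosomal RNA, 9 rose (median log2 difference 1.13, camera adjusted p = 3.92e-06). Of 24 Nup genes, which build the nuclear pore, 10 rose (median 0.81, camera adjusted p = 3.92e-06), and of 60 Eif translation initiation genes 17 rose (median 0.52, camera adjusted p = 4.64e-06). The ribosomal protein families were less clear than the fixed list of 20. Of 98 Rps genes 9 rose and 0 fell (median 0.287, camera adjusted p = 0.00787). Of 149 Rpl genes 7 rose and 1 fell (median 0.171), and that family did not pass (camera adjusted p = 0.1).

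Olfactory receptor probe sets, which the liver is not expected to express, differed between the groups: 21 of 1226 were lower and 0 higher in limma, with a median log2 difference of -0.217. Camera called the families Or (1166 genes, adjusted p = 0.00134) and Olr (75 genes, adjusted p = 0.0111) lower. With an estimated correlation neither passed (adjusted p = 0.505 and 0.503). The endothelial median of -0.204 was close to this shift in size, but these sets differ in level. Of 21 endothelial markers 15 were above background on all control arrays, whereas the olfactory receptor probe sets define the background. Under the olfactory receptor filter the endothelial list kept its call. Whether the shift reaches brighter probe sets was not tested, so its part in small list falls stays open. Of 46 RT genes, whose symbols are those of the rat major histocompatibility complex, 6 fell (median -0.39, camera adjusted p = 0.00142, adjusted p = 0.478 with an estimated correlation).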
